A study of Homo sapiens with 45 samples.

How the data were processed

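The table holds 1 value per gene and library, in RPM, and was used as given by the submitters, whose processing notes name the human genome build hg19. The aligner, the gene annotation and the rule for assigning reads to genes are not given in the sources used here. Libraries were made from poly(A) RNA selected with oligo(dT) and heat sheared, taken from several 2 mm cores per specimen, and were read for 36 bases on an Illumina GA IIx. Each of the 45 columns sums to 1000000, and the smallest step in a column gives the size of 1 read. Dividing by that step gave whole numbers for 99.988% to 100% of values per library (to within 0.05 of a read), and the whole reads recovered in this way served for library sizes and for edgeR. Whether 2 libraries of 1 subtype could be the same library read again was tested before any comparison was made: the lowest chi-square per degree of freedom was 17.2 over 140 pairs, where repeated reads of 1 library would give about 1. Specimens that differ exceed this in any case, so the test speaks only to repeats.

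Of 22144 genes or transcripts in the table, 26 with names made of numbers, which held 0.013% to 0.276% of the reads of a library, were left out because the gene cannot be known, and 102 sex-linked genes were left out because the samples come from people. That left 22016, of which 16654 reached at least 1 RPM in at least 3 libraries and were tested. No batch is given in the labels and none was put in the model. Some or all samples of 5 subtypes lie outside the shared block of title numbers. The fit restricted to that block is a check for ESS and SS, while GIST WT, TGCT and PVNS have no sample in it.

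The tests were fixed before the data were examined: limma with a trend in the prior variance on log2(RPM + 1), 9 group means fitted over 45 libraries, contrasts of each subtype with the unweighted mean of the others, and the moderated F test over all groups. All tests are two-sided unless stated, and p-values are adjusted within a comparison by the method of Benjamini and Hochberg. The unweighted mean keeps the 14 ESS libraries from setting the low side of every contrast. One shared fit was used because most groups have 3 to 6 libraries. Also fixed beforehand were 41 gene lists of cell types, pathways and tumour markers with 854 entries (837 matched exactly, 14 by an older symbol, 3 not matched), the list assigned to each comparison, the marker genes of each subtype and the rule for naming genes: the 6 highest and 4 lowest called genes with every library on 1 side of the median of the rest, the 4 with the largest gap to the next subtype, the markers, and up to 4 members of the assigned list and 3 of every other list described. All 41 lists were tested with camera in all 11 comparisons, with a preset inter-gene correlation of 0.01 and again with an estimated one, adjusted over the lists within a comparison. The lists other than the assigned one were picked for description after their tests were seen. Camera compares a list with all other genes, so its result is relative to those genes and not to 0. List medians are given relative to the median of all genes where so stated.

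Alternatives fixed beforehand were pseudocounts of 0.1 and 5 RPM, no filter, a filter at 5 RPM, median-of-ratios scaling and quantile normalization. Also fixed were robust estimation of the prior, array quality weights, the shared block alone and an equally weighted low side. A fit of the 2 compared groups alone and leaving out 1 library at a time completed them. The last was done in groups of 3 to 6 libraries, so no ESS library was left out in turn. Chosen after seeing the data were the edgeR quasi-likelihood test with TMM scaling on recovered reads, leaving out the 3 libraries dominated by 1 or 2 loci, removal of the loci above 10% of the reads of any library, leaving out MLPS replicate 3 and EMC replicate 4, and the counts of lists under each scaling. The limma and edgeR calls shared in the same direction were 886 for GIST WT, 1570 for ESS, 518 for DDLPS, 2230 for MLPS, 236 for EMC, 843 for EWS, 412 for SS and 4327 for TGCT and PVNS, then 0 for TGCT against PVNS, 195 for DDLPS against MLPS and 7 for MLPS against EMC.

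A self-test on simulated counts with known changes measured what the shared fit can find. Each gene was simulated with 1 spread for all subtypes. With 6 libraries against 39, as in GIST WT, limma recovered 10.4%, 62.7% and 86.4% of genes changed 2-, 4- and 8-fold; with the 3 of DDLPS 4.5%, 43.3% and 57.6%, and with the 4 of EWS 3%, 47.8% and 81.8%. For TGCT against PVNS it recovered 0%, 1.5% and 12.1%, and for DDLPS against MLPS 0%, 14.9% and 51.5%. The real libraries were more alike within TGCT (median correlation 0.914) and PVNS (0.936) than within subtypes in general (0.734). The values for TGCT against PVNS therefore do not apply to a fit of these 2 groups alone. Other calls numbered 8 or fewer in each simulation of 16177 to 16214 genes. A gene not called in the smaller comparisons may thus differ 4-fold or more, and the 2 calls between TGCT and PVNS say little on how alike they are.

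Analyses ran in R 4.3.3 with limma 3.58.1 and edgeR 4.0.16, and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.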

Results

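Soft tissue tumours were profiled by 3' end RNA sequencing (3SEQ), in which short reads are taken near the 3' end of polyadenylated transcripts, so that each transcript gives about 1 read whatever its length. RNA came from tissue cores of formalin-fixed, paraffin-embedded specimens. The 45 libraries carry 9 subtype labels: 6 GIST WT, 14 ESS, 3 DDLPS, 5 MLPS, 4 EMC, 4 EWS, 3 TGCT, 3 PVNS and 3 SS. The labels hold no key. The abbreviations are read here in their common soft tissue use: wild-type gastrointestinal stromal tumour, endometrial stromal sarcoma, dedifferentiated liposarcoma, myxoid liposarcoma, extraskeletal myxoid chondrosarcoma, Ewing sarcoma, tenosynovial giant cell tumour, pigmented villonodular synovitis and synovial sarcoma. There is no normal tissue among the samples, so each subtype was set against the unweighted mean of the other subtype means. TGCT and PVNS were joined when set against the rest, but counted as separate subtypes in the mean for every other subtype. In addition, 3 pairs of subtypes were compared directly. Nothing in the labels says whether samples come from separate patients, and the p-values measure the spread between these samples.

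Levels are in RPM (reads scaled to 1000000 per library), and the number after "log2" is a log2 fold change of RPM + 1 with its standard error. A gene is called higher or lower where limma gives a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 1 log2 unit. Higher or lower in a subtype refers to the mean of the other subtypes, so a single one of them can stand as high. Library sizes ran from 0.376 to 17.0 and group medians from 1.75 in GIST WT to 9.72 in PVNS, in units of 1000000 reads. The running numbers in the sample titles fall into 6 blocks, the only trace of a possible batch in the labels. GIST WT makes up 1 block alone and TGCT with PVNS another, so that neither can be told apart from its block. A block of 22 libraries holds all DDLPS, MLPS, EMC and EWS samples, 4 of ESS and 2 of SS, and values from this shared block are given beside the pooled ones.

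The subtypes differed widely in expression. Of 16654 genes tested, 10158 differed among the 9 subtypes (moderated F test, adjusted p under 0.05). For 38 of 45 libraries the most similar library carried the same label (one-sided permutation p = 1e-05, the smallest possible with 100000 permutations, whose mean was 6.4 and highest 24). The median Spearman correlation over the 1000 most variable genes was 0.734 within subtypes and 0.396 between them. All ESS, DDLPS, EWS, SS, TGCT and PVNS libraries paired within their label, as did 5 of 6 GIST WT and 3 of 5 MLPS libraries, but 0 of 4 EMC libraries. EMC replicates 2 and 3 were nearest to MLPS replicate 3, EMC replicate 4 to MLPS replicate 2 and EMC replicate 1 to DDLPS replicate 3. Principal components 1, 2 and 3 took 29.4%, 12% and 9.9% of the variance, and the first set ESS at one end with TGCT and PVNS at the other.

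**Figure D1:**
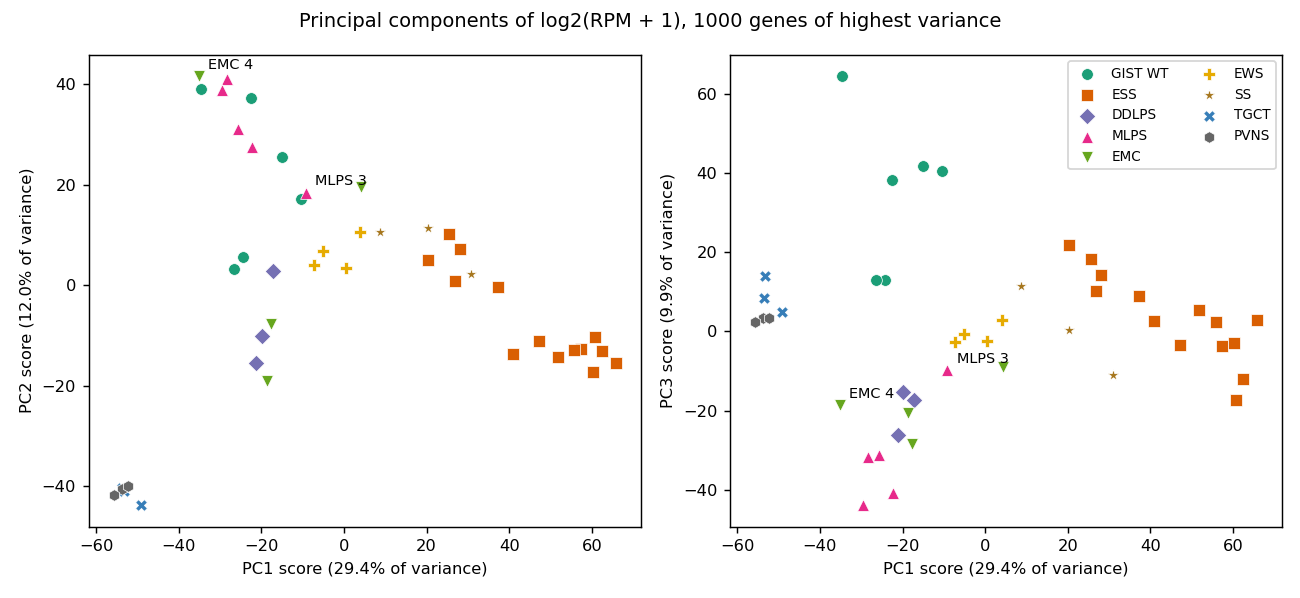
Scores of the 45 libraries on principal components 1 to 3 of log2(RPM + 1), from the 1000 genes of highest variance, with marker shape and colour by subtype. MLPS replicate 3 and EMC replicate 4 are named in the panels.

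In GIST WT (n = 6), KIT, the receptor tyrosine kinase that marks these tumours and the interstitial cells of Cajal, averaged 80.2 ± 80.7 RPM (SD) against 13.7 RPM over the other 8 subtypes (log2 2.89 ± 0.70, adjusted p = 0.0024). ANO1, the chloride channel used with KIT in diagnosis, was higher by 2.65 ± 0.53 log2 units (35.1 ± 30.7 against 1.52 RPM, adjusted p = 0.00036). The potassium channel gene KCNK3 (log2 3.56 ± 0.53) and the transcription factor genes FOXF1 (2.81 ± 0.38), HAND1 (2.41 ± 0.39) and NKX3-2 (3.73 ± 0.67) were higher too. TERT, the catalytic subunit of telomerase, stood at 263 ± 309 RPM in GIST WT and at 20.1 RPM in DDLPS, the next highest subtype (log2 4.74 ± 0.75, adjusted p = 1.97e-05). The imprinted genes IGF2 (log2 3.81 ± 0.67) and H19 (3.87 ± 0.80) were higher together, with INS-IGF2, a readthrough transcript that shares exons with IGF2 (3.98 ± 0.64).

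Of the 17 measured GIST and interstitial cell of Cajal genes, 11 were higher, 2 lower (PPP1R1A, log2 -3.39 ± 0.58, and SORBS2) and 4 not called, with the same counts over the list alone. The list median was 1.73, or 2.27 above the median of all genes (adjusted p = 6.85e-22, and adjusted p = 0.000858 with an estimated correlation). ETV1, a lineage transcription factor of these tumours, was not called (log2 1.25 ± 0.61, adjusted p = 0.112, and 1.90 without replicate 2), nor were PDGFRA (-0.99 ± 0.52, adjusted p = 0.141) and IGF1R (-0.93 ± 0.48, adjusted p = 0.134). CD34 was called at 1.73 ± 0.66 (adjusted p = 0.0445) but not without replicate 1 (1.70), 4 (1.17), 5 (1.72) or 6 (1.01). PRKCQ was called at 1.27 ± 0.30 but not without replicate 1 (0.82) or 4 (0.90). Among the genes furthest above the mean of the rest were C1QL1 (log2 4.55 ± 0.69, but -0.21 against ESS alone), AGFG2 (3.28 ± 0.64) and the cystatin gene CST1 (3.40 ± 0.83, but 1.43 without replicate 1). PRRX2 (log2 -4.75 ± 0.64), TMEM119 (-4.66 ± 0.61), CPXM1 (-4.48 ± 0.69) and MEGF6 (-4.18 ± 0.67) were furthest below among genes with every GIST WT library below the median of the rest.

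Genes of 4 broad lists were called lower in GIST WT, but no test of these lists passed with an estimated correlation. Of 40 measured cytosolic ribosomal protein genes 37 were lower, among them RPLP0 (log2 -2.84 ± 0.40), RPL32 (-2.88 ± 0.41) and RPL4 (-3.18 ± 0.49), with the same count over the list alone. Their median lay -1.36 from that of all genes (adjusted p = 4.99e-21, but adjusted p = 0.389 with an estimated correlation). Of 25 monocyte and macrophage genes 20 were lower (TYROBP -3.13 ± 0.50, CD4 -2.08 ± 0.41, CD14 -2.85 ± 0.58), again with the same count over the list alone. Their relative median was -1.22 (adjusted p = 0.000227, and adjusted p = 0.878 with an estimated correlation). Of 11 MHC class II genes, which present antigen to helper T cells, 9 were lower (HLA-DMA -2.05 ± 0.45), and 10 over the list alone. The relative median of these genes was -1.10 (adjusted p = 0.0023, and adjusted p = 0.878 with an estimated correlation). Of 8 genes of the succinate dehydrogenase complex and its assembly, SDHD was called lower (log2 -1.48 ± 0.39) and SDHB was not (-0.74 ± 0.39, adjusted p = 0.146). SDHC (-1.10 ± 0.38) lost its call without replicate 3 (-0.998), 4 (-0.84) or 5 (-1.03), and SDHAF1 (-1.13 ± 0.40) without replicate 2 (-0.82), 3 (-0.84) or 5 (-0.91). As a list these 8 lay -0.20 from all genes (adjusted p = 0.45), and edgeR called 0 of them.

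In all, 161 genes were higher and 3598 lower in GIST WT, with a median log2 fold change of all genes of -0.54. That split turned on scaling: it was 471 and 2205 with median-of-ratios scaling, 825 and 870 with quantile normalization (median 0.03), and 1046 and 736 in edgeR. The total fell to 2306 without GIST WT replicate 5. Without the 3 libraries in which 1 or 2 loci took over 40% of the reads (GIST WT replicates 2 and 5 and ESS replicate 12), 322 genes were higher and 1112 lower, with 21 ribosomal protein, 4 macrophage and 1 MHC class II genes among the lower ones. In edgeR these lists had 20, 2 and 4 genes lower, and with quantile normalization 31, 8 and 5. In mean RPM, TYROBP, CD4, CD14 and HLA-DMA were no lower in GIST WT than in the lowest other subtype (TYROBP 103 against 72.9 RPM). The GIST WT mean of CD4 leans on replicate 6, at 3.28 as log2(RPM + 1) against 1.09 in the next library. The mean of the rest includes TGCT and PVNS, where such genes are high.

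**Figure D2:**
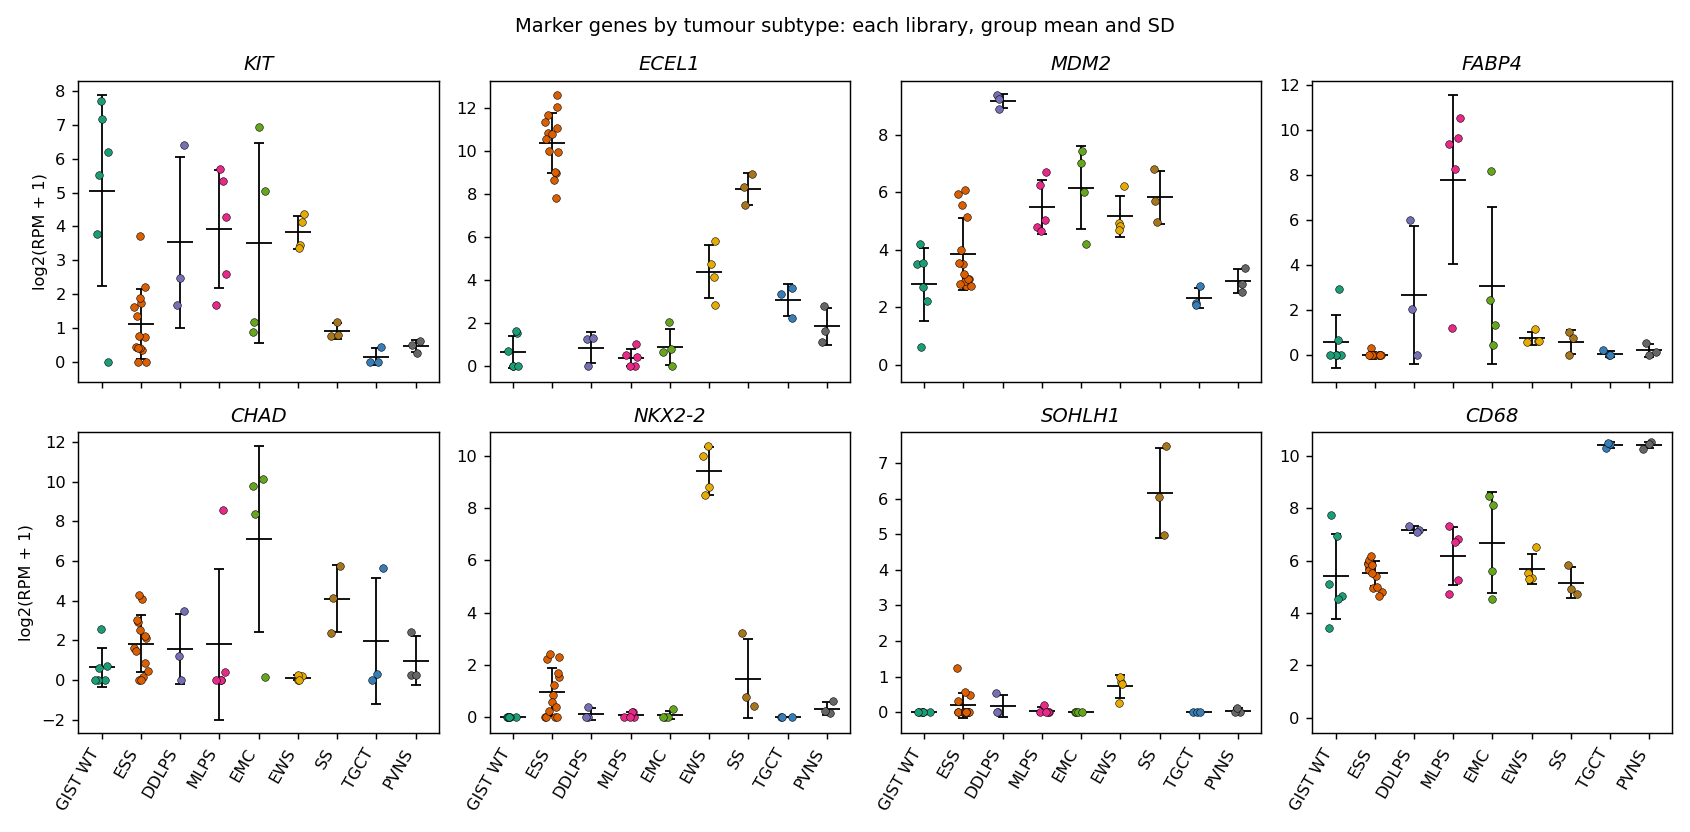
One marker gene for each subtype or pair of subtypes, as log2(RPM + 1). Dots are libraries, and bars are the group mean and SD (n = 3 to 14 per group).

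In ESS (n = 14), hormone receptor and uterine patterning genes were higher than the mean of the other subtypes. ESR1, the oestrogen receptor, averaged 23.4 ± 22.4 RPM against 0.689 RPM (log2 3.27 ± 0.33, adjusted p = 1.05e-10), and PGR, the progesterone receptor, 22.5 ± 25.7 against 0.420 RPM (3.10 ± 0.37, adjusted p = 1.25e-08). HOXA11 (log2 3.46 ± 0.30), HOXA10 (2.24 ± 0.34, at 36.9 RPM against 41.4 in MLPS), HAND2 (3.10 ± 0.35) and WT1 (2.68 ± 0.34) rose with them. FOXL2, a transcription factor of the ovary and uterus, stood at 74.6 ± 40.5 RPM against 5.03 RPM in the next highest subtype (log2 5.46 ± 0.25). The naming rule admits only genes above the median of the rest in all 14 libraries. Among these, ECEL1, an endothelin-converting enzyme-like protease, differed most (log2 7.85 ± 0.33). The glucagon receptor gene GCGR (6.55 ± 0.42), VWA5B2 (5.98 ± 0.32), COL2A1 (5.94 ± 0.55), CDK5R2 (5.89 ± 0.27) and SNCB (5.62 ± 0.38) followed.

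Of 23 measured endometrial stroma and Mullerian genes, 15 were higher in ESS, 2 lower (LRRC15 and MSX1) and 6 not called, with the same counts over the list alone. The list median was 1.23 (adjusted p = 1.64e-10, and adjusted p = 0.0413 with an estimated correlation). MME, the gene of the stromal marker CD10, was among them at 1.19 ± 0.28 (0.88 and not called in the shared block), and IFITM1 at 1.27 ± 0.44. Neither was highest in ESS: MME stood at 4.36 RPM against 4.57 in DDLPS, and IFITM1 at 1366 against 1832 in EWS. JAZF1, a fusion partner gene in low-grade tumours, was not called (log2 -0.27 ± 0.32, adjusted p = 0.587), nor was CCND1 (-0.58 ± 0.48, adjusted p = 0.421). Of 15 smooth muscle genes 8 were higher (MYLK 2.73 ± 0.43, CNN1 2.66 ± 0.47), and 8 over the list alone (adjusted p = 2.88e-05, but adjusted p = 0.206 with an estimated correlation).

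Macrophage genes were lower in ESS in 23 of 25 cases, with the same count over the list alone (AIF1 -2.21 ± 0.28, VSIG4 -2.67 ± 0.38, MARCO -3.82 ± 0.53). Their test gave adjusted p = 6.24e-17, but adjusted p = 0.149 with an estimated correlation. Of 15 iron handling genes 8 were lower (FTL -1.73 ± 0.30, SLC11A1 -1.89 ± 0.35, NCOA4 -1.77 ± 0.34, adjusted p = 2.17e-06, but adjusted p = 0.137 with an estimated correlation). MMP9 (log2 -4.90 ± 0.69), RNASE1 (-3.60 ± 0.51) and FN1 (-3.25 ± 0.56) were among the 4 lowest genes by the naming rule. Within the shared block, whose 4 ESS libraries meet neither TGCT nor PVNS, limma called 0 macrophage genes, 0 smooth muscle genes and 1 iron handling gene, against 11 Mullerian genes higher and 0 lower. There AIF1 (-0.68), VSIG4 (-0.83), MARCO (-2.56), SLC11A1 (-0.71), NCOA4 (-1.10), MMP9 (-3.42), RNASE1 (-1.22), FN1 (-2.13), MYLK (2.05) and CNN1 (2.06) were not called.

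Over all genes 1039 were higher and 677 lower in ESS. The counts were 597 and 99 within the shared block and 2196 and 834 in edgeR.

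DDLPS (n = 3) carried high levels of genes from chromosome 12q13-15, the region amplified in these tumours. MDM2, the inhibitor of p53, averaged 583 ± 99.2 RPM against 36.2 RPM over the other 8 subtypes (log2 4.86 ± 0.63, adjusted p = 7.46e-07), and the cell cycle kinase gene CDK4 118 ± 32.6 against 6.53 RPM (4.24 ± 0.45, adjusted p = 5.71e-09). CCT2 (log2 5.77 ± 0.55), FRS2 (4.96 ± 0.51), OS9 (4.21 ± 0.43), YEATS4 (3.81 ± 0.45) and TSPAN31 (3.66 ± 0.37) rose with them. Of 36 measured genes of the region 22 were higher and 0 lower (29 higher over the list alone). Their median was 2.47, or 1.95 above that of all genes (adjusted p = 1.95e-37, and adjusted p = 0.000416 with an estimated correlation). HMGA2, on the same arm, was not called (log2 2.06 ± 0.67, adjusted p = 0.0546), and its value was 0.56 without DDLPS replicate 2 and 3.54 without replicate 3. CPM was not called either (1.01 ± 0.58, adjusted p = 0.265).

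Outside 12q, C7, a component of complement, was the gene furthest above the other subtypes in DDLPS (249 ± 39.0 against 4.74 RPM, log2 6.07 ± 0.67, adjusted p = 1.77e-08), and HIF3A was higher by 4.78 ± 0.96. SLC6A8, the creatine transporter gene (log2 -3.15 ± 0.66), and ECEL1 (-2.88 ± 0.61) were lower. Of 20 fibroblast and collagen genes 6 were higher, and 14 over the list alone, with a relative median of 1.53 (adjusted p = 2.02e-06, but adjusted p = 0.425 with an estimated correlation). The calls of COL3A1 (log2 4.37 ± 0.98), DCN (4.56 ± 1.05) and SPARC (3.07 ± 0.71), and of LUM (4.74 ± 1.03), were lost without DDLPS replicate 3 (3.81, 4.37, 2.53 and 3.65), and that of DCN also without replicate 2 (3.98). Of 11 mast cell genes 6 were higher, and 8 over the list alone, with a relative median of 1.42 (adjusted p = 0.000114, but adjusted p = 0.402 with an estimated correlation). HPGDS, a prostaglandin D synthase gene (1.71 ± 0.29), and the protease genes CTSG (3.54 ± 0.88) and CPA3 (1.94 ± 0.52) lost their calls without replicate 1 (0.96, 1.51 and 0.14).

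Of 20 called genes taken by the naming rule in DDLPS, 11 kept their call whichever DDLPS library was left out. The totals of 838 higher and 12 lower (median over all genes 0.52) fell to 356 genes without replicate 2 and 158 without replicate 3. They were 130 and 18 with median-of-ratios scaling (median 0.08), 115 and 25 with quantile normalization and 221 and 57 within the shared block. Genes of 12q called higher numbered 18, 17 and 18 in these 3 settings, and mast cell genes 1 in each, while edgeR called 9 mast cell genes higher.

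**Figure D3:**
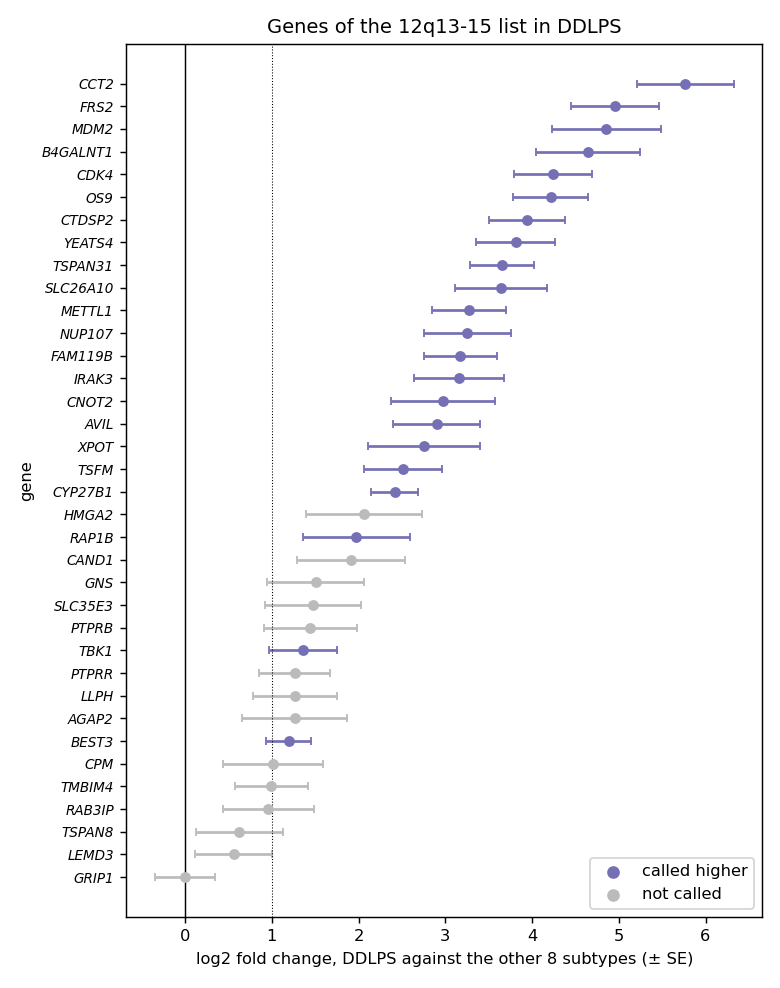
Log2 fold change (± SE) of the 36 measured genes of the chromosome 12q13-15 list in DDLPS (n = 3) against the other 8 subtypes. Filled colour marks genes called higher, grey those not called, and the dotted line the threshold of 1 log2 unit.

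In MLPS (n = 5), genes of fat cells were higher than elsewhere. FABP4, the fatty acid binding protein of adipocytes, averaged 649 ± 555 RPM against 12.3 RPM (log2 6.80 ± 0.79, adjusted p = 3.87e-08). LPL, which releases fatty acids from lipoproteins, was higher by 5.67 ± 0.64 and ADIPOQ, the gene of adiponectin, by 4.14 ± 0.65. PLIN1, which coats lipid droplets, was higher by 3.80 ± 0.48, and PPARG, the master regulator of fat cell differentiation, by 4.58 ± 0.47. Of 25 measured adipocyte genes 19 were higher and 0 lower (20 over the list alone). Their median was 2.77, or 2.50 above that of all genes (adjusted p = 3.6e-16, but adjusted p = 0.0758 with an estimated correlation). MLPS replicate 3 lacked these levels (FABP4 1.23 as log2(RPM + 1), against 8.26 in the next lowest library). Without it and EMC replicate 4, a choice made after seeing the data, FABP4 stood at 8.65, LPL at 7.28 and the relative median at 3.23.

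DDIT3, the fusion gene of this tumour, was called (log2 1.86 ± 0.56, adjusted p = 0.0173) but not without MLPS replicate 3 (1.65) or 4 (1.89), or in the shared block (1.59). The receptor tyrosine kinase gene RET (4.41 ± 0.51) and the cancer-testis antigen genes PRAME (4.01 ± 0.62) and CTAG1B (2.30 ± 0.39) were higher. So were KLHDC8A (log2 5.24 ± 0.51), SMOC1 (4.91 ± 0.66), SLC25A18 (4.71 ± 0.72), MYH15 (4.24 ± 0.48) and the pseudogene SLC6A10P (5.91 ± 0.91). EMP3 (log2 -4.06 ± 0.63), PCSK1N (-4.05 ± 0.84), CPNE7 (-3.96 ± 0.95) and CLEC11A (-3.96 ± 0.65) were lower.

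Ribosomal protein genes were higher in MLPS in 24 of 40 cases (RPL30 2.49 ± 0.48, RPS23 2.42 ± 0.49, RPS6 2.09 ± 0.42), and 28 over the list alone. Their relative median was 1.13 (adjusted p = 7.91e-10, but adjusted p = 0.355 with an estimated correlation). Of 32 oxidative phosphorylation genes, which encode the respiratory chain and ATP synthase, 13 were higher (ATP5A1 2.28 ± 0.48, UQCRH 2.15 ± 0.46, ATP5C1 1.89 ± 0.42), and 16 over the list alone. The relative median was 0.78 (adjusted p = 0.00201, but adjusted p = 0.492 with an estimated correlation). In the shared block 15 adipocyte, 5 ribosomal protein and 1 oxidative phosphorylation genes were called. RPL30 (1.10), RPS23 (1.39), RPS6 (1.24), ATP5A1 (1.37), UQCRH (1.24) and ATP5C1 (1.09) were not. The totals of 2427 higher and 341 lower (median over all genes 0.28) became 385 and 277 in the block, 1124 and 757 with quantile normalization (median -0.04) and 684 in all without MLPS replicate 4.

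As labelled, EMC (n = 4) was the least uniform subtype (median correlation within the label 0.476, against 0.593 in GIST WT, the next lowest), and few of its genes were called. The low value rests in part on EMC replicate 4. Its median correlation was 0.431 with EMC replicates 1 to 3 and 0.859 with the MLPS libraries other than replicate 3. EMC replicates 1, 2 and 3 had medians of 0.57, 0.599 and 0.684 with each other. COX6A2, a muscle form of a respiratory subunit (log2 3.26 ± 0.53, adjusted p = 0.000582), the joint morphogen gene GDF5 (3.19 ± 0.52, adjusted p = 0.000582) and PGAM2, a muscle glycolytic enzyme gene (4.34 ± 0.76, adjusted p = 0.000929), were higher. MFAP4 (log2 -3.24 ± 0.54) and ECEL1 (-2.85 ± 0.54) were lower. Of 24 called genes taken by the naming rule, these 5 alone kept their call whichever EMC library was left out. CHAD, the gene of the cartilage protein chondroadherin, averaged 577 ± 506 RPM against 16.0 RPM (log2 5.47 ± 1.09, adjusted p = 0.00441), but was not called without EMC replicate 2 (5.05) or 3 (4.58). ACAN, the gene of aggrecan (3.93 ± 0.98), was not called without EMC replicate 1 (2.19), 2 (3.87) or 3 (3.60), and stood at 6.05 without replicate 4. HAPLN1, a link protein gene (2.77 ± 0.58), lost its call without replicate 1 (1.54) or 3 (2.24), and SOX9, the transcription factor of chondrocytes (1.75 ± 0.47), without 1 (1.90), 2 (1.59) or 3 (0.99). NR4A3, the fusion gene of this tumour, was not called (log2 1.39 ± 0.53, adjusted p = 0.169), with 0.58 without replicate 3 and 2.16 without replicate 4.

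Of 18 cartilage genes 4 were higher in EMC, and 10 over the list alone. Their median was 1.67, or 1.51 above all genes (adjusted p = 3.36e-07, but adjusted p = 0.25 with an estimated correlation). Of 27 neuroendocrine and neuronal genes 1 was higher, and 2 over the list alone. That gene, CPE, a prohormone processing enzyme (log2 3.06 ± 0.67, adjusted p = 0.0103), lost its call without EMC replicate 2 (2.88) or 3 (2.20). The median (-0.17) and mean (0.14) of this list and the direction of its test (lower, adjusted p = 0.454) differ in sign. NMB, the gene of the neuropeptide neuromedin B and a marker set beforehand, was called (4.45 ± 0.98, adjusted p = 0.0104) but not without replicate 2 (3.24) or 3 (3.21) or in the shared block (3.80). INSM1 (1.53 ± 0.47, adjusted p = 0.0844), PCSK2 (1.38 ± 0.66), CHRNA6 (0.61 ± 0.46), S100B (1.55 ± 0.64) and SYP (-0.57 ± 0.46) were not called.

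In EMC 3 further lists held called genes. Of 20 skeletal muscle genes 2 were higher, and 10 over the list alone, with a relative median of 1.04 (adjusted p = 1.07e-06, but adjusted p = 0.325 with an estimated correlation). Of 32 oxidative phosphorylation genes 6 were higher, and 13 over the list alone, with a relative median of 0.69 (adjusted p = 1.93e-06, but adjusted p = 0.325 with an estimated correlation). ATP5B (2.16 ± 0.47) lost its call without EMC replicate 2 (1.96) or 3 (1.89). Of 18 immediate early genes, which respond within minutes to stimuli, 3 were higher, and 7 over the list alone, with a relative median of 1.17 (adjusted p = 3.02e-05, but adjusted p = 0.437 with an estimated correlation). EGR3 (2.45 ± 0.50) lost its call without replicate 2 (1.99) or 3 (2.24), and MYC (2.45 ± 0.51) likewise (2.20 and 1.95).

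The EMC total of 230 higher and 9 lower (median over all genes 0.16) fell to 51 without replicate 2 and 19 without replicate 3, and rose to 782 without replicate 4. It was 6 and 28 in the shared block, 121 and 20 with quantile normalization (median -0.05) and 1292 and 41 in edgeR. In the block limma called 0 genes of the cartilage, muscle, respiratory, neuroendocrine and immediate early lists, while edgeR on every library called 14 cartilage and 13 skeletal muscle genes.

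**Figure D4:**
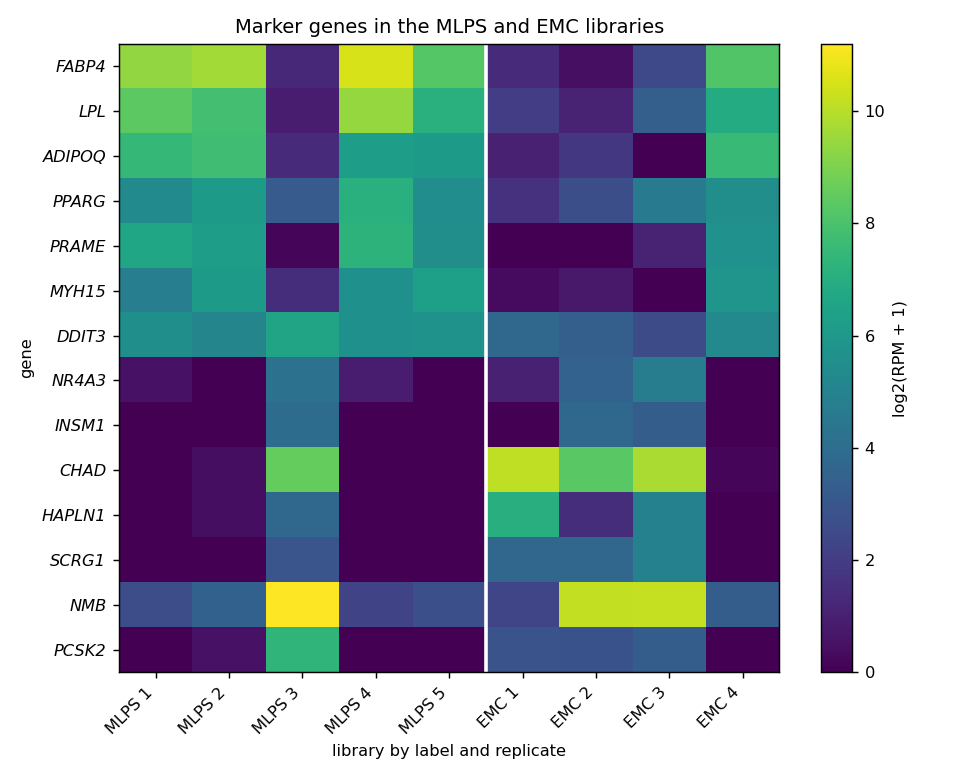
Levels of 14 marker genes as log2(RPM + 1) in the 5 MLPS and 4 EMC libraries. In MLPS replicate 3 and EMC replicate 4 most of these genes follow the other label.

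Compared directly with EMC, MLPS was lower in cartilage genes and higher in fat cell genes as groups. The 18 cartilage genes had a median of -2.12 (adjusted p = 2.47e-19, and adjusted p = 0.0113 with an estimated correlation) and the 25 adipocyte genes of 1.29 (adjusted p = 7.85e-16, and adjusted p = 0.0455 with an estimated correlation). Limma called 0 single genes of either list, and edgeR 6 cartilage genes and 0 adipocyte genes, while 10 cartilage genes were lower and 11 adipocyte genes higher over the list alone. FABP4 stood at 4.71 ± 1.10 (adjusted p = 0.0587), PLIN1 at 2.78 ± 0.66, ACACB at 2.97 ± 0.75, CHAD at -5.30 ± 1.38 (adjusted p = 0.106) and NR4A3 at -1.19 ± 0.67 (adjusted p = 1). PPARG was at 1.85 ± 0.66 (1.18 without EMC replicate 1), DDIT3 at 1.96 ± 0.78, ACAN at -4.40 ± 1.24 (-2.66 without EMC replicate 1) and HAPLN1 at -2.54 ± 0.73 (-1.32 without EMC replicate 1). The 27 neuroendocrine and neuronal genes gave 0 calls in limma and 0 in edgeR, and a median of -0.22 (adjusted p = 0.0407, but adjusted p = 0.46 with an estimated correlation).

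Among single genes 18 were higher and 6 lower in MLPS than in EMC. EGFL6 (log2 3.30 ± 0.60, adjusted p = 0.00847) and MFAP4, a microfibril protein gene (3.43 ± 0.68, adjusted p = 0.0193), were higher, and SLURP1 (-2.79 ± 0.50, adjusted p = 0.00847) and the cartilage gene SCRG1 (-2.48 ± 0.52, adjusted p = 0.029) lower. None of the 10 called genes taken by the naming rule kept its call whichever library was left out. Without EMC replicate 3 none was called, with EGFL6 at 3.23, MFAP4 at 3.67, SLURP1 at -1.77 and SCRG1 at -1.87. The total of 24 was 1 in the shared block and 5 with median-of-ratios scaling. It was 45 in edgeR and 0 by limma with the 2 groups fitted alone. In the limma fit of all groups 891 of 16654 genes had an unadjusted p under 0.05. A share of 0.05 would pass that limit by chance, so 891 is little more than chance gives.

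In MLPS replicate 3 and EMC replicate 4 fat cell and cartilage genes run against the label. With both left out, a choice made after seeing the data, 277 genes were higher and 317 lower in MLPS than in EMC, with 14 adipocyte genes higher and 10 cartilage genes lower. FABP4 then stood at 8.04, CHAD at -9.31 and NR4A3 at -2.72. Against the other subtypes, EMC then gave 869 genes, with 10 cartilage genes and 8 skeletal muscle genes higher, and NR4A3 (2.26), INSM1 (2.21) and PCSK2 (2.31) were called.

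EWS (n = 4) held the largest log2 fold change of any gene named in the fit of all libraries. NKX2-2, a neural transcription factor and known target of the EWSR1-FLI1 fusion, averaged 785 ± 460 RPM against 0.622 RPM (log2 9.03 ± 0.38, adjusted p = 1.53e-23). PAX7, a transcription factor of muscle progenitors, averaged 354 ± 358 against 0.421 RPM (7.57 ± 0.34, adjusted p = 1.15e-22). Differences of similar size were seen in UGT3A2 (log2 8.86 ± 0.57), HAP1 (8.45 ± 0.69), PGLYRP2 (8.002 ± 0.59), C1QL2 (7.33 ± 0.48) and CALCA, the calcitonin gene (7.41 ± 0.76). The neuropeptide receptor gene NPY1R (5.47 ± 0.38), LOXHD1 (6.76 ± 0.32), LIPI (3.99 ± 0.19), NR0B1 (2.62 ± 0.25), PRKCB (4.17 ± 0.66), BCL11B (4.22 ± 0.42) and the cyclin gene CCND1 (3.47 ± 0.79) were also higher. The small heat shock protein gene HSPB7 (log2 -4.11 ± 0.77) and INS-IGF2 (-3.53 ± 0.76) were lower.

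Of 28 measured EWSR1-FLI1 activated genes 19 were higher and 0 lower in EWS (20 higher and 1 lower over the list alone). Their median was 2.57, or 2.48 above all genes (adjusted p = 2.49e-34, and adjusted p = 9.67e-10 with an estimated correlation), and 17 were higher within the shared block. CD99, the membrane marker used in diagnosis, was called at 1.52 ± 0.42 (adjusted p = 0.0187) but not without EWS replicate 1 (1.36), 2 (1.52) or 4 (1.58). STEAP1 was called at 2.12 ± 0.57 but not without replicate 3 (1.28) or in the block (2.06). FLI1, whose 3' end is part of the fusion, was not called (log2 0.21 ± 0.51, adjusted p = 0.883).

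Of 30 proliferation genes 7 were higher in EWS, and 14 over the list alone (adjusted p = 4.31e-07, but adjusted p = 0.466 with an estimated correlation). CCNB1 (1.31 ± 0.32) lost its call without EWS replicate 1 (1.21) or 3 (1.09), and CCNB2 (1.97 ± 0.51) without 2 (1.77) or 4 (1.87). Of 28 genes of the BAF chromatin remodelling complex 5 were higher, among them DPF3 (1.66 ± 0.21) and BCL11B (adjusted p = 0.00244, but adjusted p = 0.466 with an estimated correlation). Of 40 ribosomal protein genes 7 were higher, and 20 over the list alone (adjusted p = 9.13e-10, but adjusted p = 0.466 with an estimated correlation). RPLP0 (1.71 ± 0.48) lost its call without replicate 2 (1.42) or 4 (1.62), and within the shared block limma called 0 of these genes (RPLP0 1.16). Of 20 fibroblast and collagen genes 2 were lower, and 4 over the list alone (adjusted p = 5.58e-05, but adjusted p = 0.466 with an estimated correlation). They were COL6A2 (log2 -2.31 ± 0.51) and COL6A1 (-1.71 ± 0.41, not called without replicate 2 at -1.59), and MMP2 was not called (-2.25 ± 0.81, adjusted p = 0.0975).

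Of 32 called genes taken by the naming rule in EWS, 18 kept their call whichever EWS library was left out. EWS replicates 2 and 4 had a Spearman correlation of 0.972, the highest of any library with its nearest, against a median of 0.743 within EWS. The labels do not say whether they come from the same tumour. If so, EWS would hold fewer independent samples than its p-values assume. The total of 875, 724 genes higher and 151 lower, was 513, 506 and 522 without EWS replicates 1, 2 and 4. The split was 472 and 379 within the shared block, 743 and 409 with quantile normalization and 1263 and 351 in edgeR.

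In SS (n = 3), SOHLH1, a transcription factor gene of germ cells, averaged 90.9 ± 77.0 RPM against 0.676 RPM in the next highest subtype (log2 6.02 ± 0.26, adjusted p = 2.42e-23). FGFR3, a fibroblast growth factor receptor gene, averaged 738 ± 197 against 91.5 RPM (6.08 ± 0.81, adjusted p = 1.15e-06). PRSS21 (log2 6.06 ± 0.86), ESPN (5.92 ± 0.69) and COL2A1 (5.87 ± 1.03, at 348 RPM against 686 in ESS) were about as far above the mean of the rest. TLE1, the corepressor used in diagnosis, was higher by 3.30 ± 0.56 (60.1 ± 54.9 against 4.68 RPM, adjusted p = 0.00013). WIF1, a secreted Wnt inhibitor (log2 4.78 ± 0.72), the potassium channel gene KCNT1 (4.63 ± 0.71) and the mucin gene MUC6 (4.82 ± 0.60) were higher too.

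SSX1, a fusion partner gene, was called in SS at 1.27 ± 0.24 but stood at 0.72 without SS replicate 2 and 1.93 without replicate 1. KRT19, an epithelial keratin gene, was called at 4.72 ± 1.22 (adjusted p = 0.0196) but not without replicate 2 (4.61) or 3 (3.51). Of 27 synovial sarcoma and Wnt target genes 10 were higher and 0 lower (19 over the list alone). Their median was 1.59, or 1.33 above all genes (adjusted p = 6.69e-16, and adjusted p = 0.00136 with an estimated correlation). BCL2 (1.55 ± 0.49, adjusted p = 0.0708), SIM2 (2.07 ± 0.72, adjusted p = 0.114) and FZD10 (0.88 ± 0.31, adjusted p = 0.125) were not called. NUPR1 (log2 -3.62 ± 0.58), SRPX2 (-3.45 ± 0.69) and DPYSL3 (-3.17 ± 0.65) were lower.

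Cancer-testis antigens, genes silent in most adult tissue outside the testis, were higher in SS in 6 of 15 cases (PRAME 4.61 ± 0.78, MAGEA4 2.40 ± 0.23), and 8 over the list alone. Their relative median was 0.77 (adjusted p = 7.56e-07, and adjusted p = 0.00546 with an estimated correlation). Of 12 gastrointestinal mucosa genes 2 were higher, MUC6 and MUC2, and 5 over the list alone, with a relative median of 0.65 (adjusted p = 0.000168, and adjusted p = 0.00546 with an estimated correlation). MUC2 (1.501 ± 0.30) lost its call without SS replicate 2 (0.61), and CDH17 was not called (1.32 ± 0.42, adjusted p = 0.0708). Macrophage genes were lower in 7 of 25 cases, and 16 over the list alone. The list lay at a relative median of -1.99 (adjusted p = 1.56e-21, and adjusted p = 0.0463 with an estimated correlation). AIF1 (-2.72 ± 0.51) and C1QC (-3.04 ± 0.69) lost their calls without replicate 2 (-2.26 and -2.76).

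In SS 399 genes were higher and 71 lower (median over all genes 0.26), against 258 and 160 with median-of-ratios scaling (median 0.02) and 285 and 200 with quantile normalization. The total of 470 was 199 without SS replicate 1 and 206 without replicate 2. Within the shared block, with 2 SS libraries, the counts were 119 and 37, with 2 synovial sarcoma genes higher and, by limma, 0 macrophage genes lower. There FGFR3 (4.52), COL2A1 (4.19), WIF1 (3.43), KCNT1 (3.48), TLE1 (1.63), PRAME (3.83), AIF1 (-2.10) and C1QC (-2.26) were not called.

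TGCT and PVNS (n = 3 each) shared a profile of macrophages and synovial lining. CSF1R, the receptor for macrophage colony-stimulating factor, averaged 3920 ± 640 RPM against 217 RPM over the other 7 subtypes (log2 5.17 ± 0.57, adjusted p = 2.25e-09). Its ligand CSF1, whose gene is rearranged in these tumours, averaged 126 ± 168 against 2.24 RPM (4.25 ± 0.50, adjusted p = 1.07e-08). CD68 (log2 4.45 ± 0.42), TYROBP (5.50 ± 0.50), TREM2 (5.87 ± 0.56) and AIF1 (4.24 ± 0.38), genes of macrophages, rose with them, while CD163, a scavenger receptor of the same cells, was not called (0.65 ± 0.44, adjusted p = 0.237). PRG4, the joint lubricant lubricin, stood at 115 ± 25.6 against 0.781 RPM (log2 6.33 ± 0.29, adjusted p = 7.1e-22), and CLU was higher by 3.56 ± 0.83. Large differences were also seen in PLA2G2A, a secreted phospholipase gene (6.64 ± 0.76), MMP9 (6.59 ± 0.95), MARCO (6.52 ± 0.73), TREM1 (6.26 ± 0.62) and WISP2 (5.995 ± 0.58).

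Of 25 monocyte and macrophage genes 21 were higher and 0 lower in TGCT and PVNS. Their median was 4.24, or 4.78 above all genes (adjusted p = 2.65e-41, and adjusted p = 0.00298 with an estimated correlation). MHC class II genes were higher in 10 of 11 cases (HLA-DMA 4.25 ± 0.45, CD74 4.38 ± 0.51, CIITA 3.86 ± 0.46), with a relative median of 4.03 (adjusted p = 3.34e-21, and adjusted p = 0.00298 with an estimated correlation). Synovial lining genes were higher in 10 of 18 cases (CRTAC1 3.08 ± 0.33) and lower in 1 (SEMA3A), with a relative median of 2.79 (adjusted p = 9.85e-15, and adjusted p = 0.00101 with an estimated correlation). Osteoclast genes were higher in 9 of 13 cases (ACP5 4.80 ± 0.76, OSCAR 3.91 ± 0.46, TNFRSF11A 1.97 ± 0.20, SIGLEC15 1.54 ± 0.21), with a relative median of 1.97 (adjusted p = 6.12e-14, and adjusted p = 0.0041 with an estimated correlation). All 4 lists gave the same counts over the list alone. CTSK, the main collagen protease of osteoclasts, was not called (log2 0.36 ± 0.70, adjusted p = 0.699).

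Of 15 T cell genes 7 were higher in TGCT and PVNS, and 8 over the list alone, with a relative median of 1.59 (adjusted p = 1.47e-08, and adjusted p = 0.0468 with an estimated correlation). CD27 (2.57 ± 0.44) and CD3E (2.83 ± 0.54) were among them, and LCK (1.30 ± 0.23), which is not called without PVNS replicate 3 (0.84). Of 15 iron handling genes 6 were higher (SLC11A1 4.36 ± 0.48, HAMP 3.43 ± 0.42, FTL 3.02 ± 0.41) and 2 lower (TFRC and NCOA4). Their relative median was 1.20 (adjusted p = 1.45e-06, and adjusted p = 0.0456 with an estimated correlation). EEF1A2 (log2 -4.54 ± 0.96), INS-IGF2 (-4.52 ± 0.64), C1QL1 (-4.39 ± 0.69) and SEMA4G (-4.31 ± 0.45) were the 4 lowest genes by the naming rule. In total 914 genes were higher and 4620 lower, with a median over all genes of -0.54. The split was 1657 and 2780 with median-of-ratios scaling (median -0.22), 1606 and 1461 with quantile normalization (median -0.08) and 2026 and 3872 in edgeR.

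Between TGCT and PVNS 2 genes were called. CD177, a surface protein gene of neutrophils, was higher in TGCT (116 ± 131 against 2.90 RPM, log2 4.66 ± 0.80, adjusted p = 0.00829) and HLA-DRB6, an MHC class II pseudogene, lower (-2.82 ± 0.50, adjusted p = 0.00829). CD177 lost its call without TGCT replicate 2 (4.501) or 3 (3.61) or PVNS replicate 1 (4.27) or 2 (4.09), and HLA-DRB6 without TGCT replicate 1 (-2.64) or 2 (-2.64) or PVNS replicate 3 (-2.22). Of 16654 genes, 820 had an unadjusted p under 0.05 in limma, no more than the share of 0.05 that chance gives. EdgeR called 0, with 1817 under that limit. Not called were CSF1 (log2 0.12 ± 0.92), CSF1R (-0.03 ± 1.04), CD68 (0 ± 0.77), CD163 (-0.56 ± 0.81), PRG4 (-0.30 ± 0.54), CLU (-0.76 ± 1.52) and CTSK (0.81 ± 1.29). MMP9 stood at 1.31 ± 1.73, with 0.71 without TGCT replicate 3, 2.12 without PVNS replicate 1 and 0.73 without PVNS replicate 3. ACP5, the tartrate-resistant phosphatase of osteoclasts, was at 2806 ± 289 RPM in TGCT and 315 RPM in PVNS, also not called (3.36 ± 1.39, adjusted p = 0.837).

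By list, limma and edgeR each called 0 of 25 macrophage genes between TGCT and PVNS (median -0.22, or -0.05 relative to all genes, adjusted p = 0.771). CD4 stood at -2.41 ± 0.75 (adjusted p = 0.557), AIF1 at -1.51 ± 0.70 and VSIG4 at -1.70 ± 0.94. Osteoclast genes gave 0 calls of 13 and a relative median of 0.95 (adjusted p = 0.00997, but adjusted p = 1 with an estimated correlation), with OSCAR at 1.27 ± 0.85 and TNFRSF11A at -0.85 ± 0.36. Ribosomal protein genes gave 0 of 40 and -0.63 (adjusted p = 0.000719, but adjusted p = 1 with an estimated correlation), with RPS27 at -2.94 ± 0.96 and RPL37 at -2.74 ± 0.86. Over each of these lists alone 0 genes passed as well. How far TGCT and PVNS differ depends on the spread the test uses. Depth also goes with the label. TGCT libraries had at most 5635384 reads and 14884 genes detected, PVNS libraries at least 9672088 reads and 17384 genes. In fits of TGCT against PVNS, depth can therefore not be told apart from the subtype. Fitted alone, with their own spread, the 6 libraries gave 314 genes higher and 527 lower in TGCT, with ACP5 called higher, AIF1, VSIG4, RPS27 and RPL37 called lower, and CD177 not called. The median over all genes was -0.17, and the counts with the shared spread were 2 higher and 7 lower with median-of-ratios scaling (median -0.30) and 4 and 1 with quantile normalization (median 0.04).

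Of the 2 liposarcomas, DDLPS held the 12q genes and MLPS the fat cell genes. MDM2 stood at 583 RPM in DDLPS (n = 3) against 52.4 RPM in MLPS (n = 5) (log2 3.69 ± 0.76, adjusted p = 0.00375), and CDK4 at 118 against 10.2 RPM (3.51 ± 0.54, adjusted p = 6.8e-05). TSPAN31 (log2 3.71 ± 0.45), OS9 (3.61 ± 0.53), B4GALNT1 (5.85 ± 0.72) and CYP27B1, the enzyme gene that activates vitamin D (2.34 ± 0.33), went with them. LPL (log2 -5.33 ± 0.97) and ACACB, an acetyl-CoA carboxylase gene of fat metabolism (-4.18 ± 0.82), were lower in DDLPS. FABP4 (-5.11 ± 1.20) was lower as well, but not called without DDLPS replicate 1 (-3.77) or 3 (-4.80) or in the shared block, and PPARG (-3.65 ± 0.72) not without DDLPS replicate 1 (-2.95). Among genes taken by the naming rule, STRA6, a retinol uptake receptor gene (log2 6.68 ± 0.89), and C7 (6.55 ± 0.81) differed most toward DDLPS, and SLC6A10P (-7.56 ± 1.38), KLHDC8A (-5.83 ± 0.77) and SMOC1 (-5.56 ± 1.003) toward MLPS. HMGA2 was not called (2.78 ± 0.81, adjusted p = 0.0574, with 1.28 without DDLPS replicate 2 and 4.26 without replicate 3), nor was DDIT3 (-0.05 ± 0.85, adjusted p = 0.995).

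Of 36 genes of 12q13-15, 18 were higher in DDLPS than in MLPS and 0 lower (23 over the list alone). Their median was 2.13, or 1.96 above all genes (adjusted p = 1.36e-30, and adjusted p = 0.00188 with an estimated correlation). Of 25 adipocyte genes 12 were lower (16 lower and 1 higher over the list alone), with a relative median of -2.38 (adjusted p = 2.24e-21, and adjusted p = 0.0099 with an estimated correlation). Cancer-testis antigens were lower in 4 of 15 cases (PRAME -4.97 ± 0.95), with the same count over the list alone and a relative median of -0.26 (adjusted p = 0.000389, but adjusted p = 0.0882 with an estimated correlation). Limma called 0 of 40 ribosomal protein genes, and edgeR 0 (RPS27 -2.78 ± 0.86, RPL3 -2.37 ± 0.77), with 4 lower over the list alone. The list lay at a relative median of -1.52 (adjusted p = 1.99e-20, but adjusted p = 0.217 with an estimated correlation).

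Between DDLPS and MLPS 179 genes were higher and 135 lower (median over all genes 0.16), against 105 and 150 with median-of-ratios scaling (median -0.08), 163 and 81 with the shared block fitted alone and 46 and 18 with the 2 groups fitted alone. In the block 16 genes of 12q, 5 adipocyte genes and 1 cancer-testis antigen were called. The total of 314 was 198 without DDLPS replicate 1 and 127 without replicate 3. Of 21 called genes taken by the naming rule, 15 kept their call whichever library was left out.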

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

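The tests of MLPS replicate 3 with EMC replicate 4, of the reads on RNF168, LRRC16A and S1PR2, and of these 3 loci as the source of the shift in GIST WT were chosen only after the result was seen.

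A value was picked out where the most extreme library of a group of 4 to 10 stood further from its nearest neighbour, as a share of the group's range, than Dixon's 95% limit allows. That held for 24 of 194 values (12.4%), where chance gives about 1 in 20. In MLPS, replicate 3 was the lowest library for FABP4 (share of the range 0.756), LPL (0.728), ADIPOQ (0.739), PRAME (0.758), HOXA5 (0.732) and ACACB (0.811). It was the highest for CHAD (0.954), HAPLN1 (0.894), NR4A3 (0.781), CPNE7 (0.872), SCRG1 (1), INSM1 (1) and SLURP1 (1), with the other 4 libraries listed at 0 for the last 3 and the value of SLURP1 resting on 1 read. In EMC, replicate 4 was the lowest for PCSK2 (0.854) and the highest for MYH15 (0.866), and replicate 3 the highest for CHRNA6 (0.885) and for the percent of reads on the 3 loci named above (0.872, at 1.62% against 0.8% in the next). In GIST WT, replicate 1 was the highest for CST1 (0.835), and replicate 6 for PRRX2 (0.708), CD4 (0.667), HLA-DMB (0.866) and PPP1R1A (1, from 4 reads, with the other 5 at 0). In EWS, replicate 1 was the lowest for FLI1 (0.939) and replicate 3 the highest for MMP2 (0.879).

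MLPS replicate 3 and EMC replicate 4 carry marker genes of the other subtype, and their titles have consecutive numbers. Of 594 genes called between the other 4 MLPS and 3 EMC libraries, 84.8% in MLPS replicate 3 and 85.4% in EMC replicate 4 lay nearer the mean of the other label, which is what a swap of the 2 labels would give. Genes of a library's own label were placed on a scale from the other label (0) to its own (1). Their median position was -0.01 in MLPS replicate 3 and -0.02 in EMC replicate 4. In MLPS replicate 3 this argues against RNA of the other subtype mixed into the library. In EMC replicate 4 it cannot decide, since EMC replicate 1 sat near the other label as well. The other MLPS libraries had 4.8% to 18.5% of genes nearer the other label and positions of 0.47 to 1.12, but EMC replicate 1 had 55.7% and 0.03, so these 2 do not stand alone in EMC. A swap may account for the pattern but cannot be told from 2 tumours that differ from their diagnosis, and no biological explanation was tested.

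In GIST WT replicates 2 and 5 and ESS replicate 12, RNF168 (47.51% and 57.35% of the reads) or LRRC16A with S1PR2 (78.31% together) took over 40% of the library. Expression of these genes as a property of the subtype stays open for RNF168, since 9 of 20 GIST WT and ESS libraries (2 of 6 and 7 of 14) lay below 1.89%, the highest library of the other 7 subtypes, and the rest above, while for LRRC16A and S1PR2 only 1 of the 20 lay above the highest library of the others (3.87% and 2.53%). The share of the 3 loci fell with the number of reads over the 45 libraries (Spearman rho = -0.509, permutation p = 0.00057, adjusted over 7 such relations 0.00199; Pearson r = -0.327, p = 0.0397, adjusted 0.0556, and r = -0.38 without the 2 libraries farthest from the median depth). Within number blocks rho was -1 in 7 ESS libraries (exact p = 0.000397), -0.657 in GIST WT (p = 0.175), -0.829 in TGCT and PVNS (p = 0.0583) and -0.271 in the shared block (p = 0.221), and the last 3 do not pass, though Pearson r in TGCT and PVNS does (-0.929, p = 0.00694, adjusted 0.0243). An excess that goes with a low yield of reads may account for part of this. GIST WT replicate 2 and ESS replicate 12, with RNF168, had the fewest reads (405941 and 375572). GIST WT replicate 5, with LRRC16A and S1PR2, had 1871339. Each shallower library held less on the 3 loci, such as GIST WT replicate 4 (1621392 reads, 7.33%) and SS replicate 3 (1574544 reads, 1.1%). For LRRC16A and S1PR2 a low yield thus rests on 1 library and stays open. The permutations ignore the labels, and TGCT differs from PVNS in both depth and share. The values there and over 45 libraries thus mix depth with subtype. What produces the excess was not tested.

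More genes were lower than higher in GIST WT and in TGCT with PVNS (median log2 fold change of all genes -0.54 in each). Depth is argued against in TGCT and PVNS, where thinning every library to 1000000 reads outside the 3 loci left -0.512 (quartiles over genes -1.128 and -0.075). Without the 100 genes of highest level there (43.6% of reads, against 32.9% in the other subtypes), the median was -0.416 (quartiles -1.08 and 0.075). These quartiles give the spread over genes, not the uncertainty of the median. The median lay beyond the limit set beforehand for arguing against these genes, so a shift remained without them. Whether they account for part of it stays open. In GIST WT the median was -0.306 with the loci removed and the rest rescaled (quartiles -0.75 and 0.136), so a shift remained there too. Whether the loci account for the rest stays open, as does depth. Thinned to 1000000 reads the median was -0.144, but only 4 of 6 libraries had the reads. Leaving out the 3 dominated libraries, with no thinning, gave -0.25, so the thinned value mixes depth with the loss of libraries. As both groups have a title block to themselves, a batch cannot be told apart from the subtype, and no biological explanation was tested beyond that label.

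Whether chance can be excluded was asked with other splits of the same libraries into groups of the same sizes, the real one counted in. For the comparisons with the rest, 1 of 100 splits gave as many called genes in GIST WT (3759, highest other split 3385), ESS (1716, 498), MLPS (2768, 280), EMC (239, 135), EWS (875, 354) and TGCT with PVNS (5534, 543). The share was 2 of 100 in DDLPS (850) and 3 of 100 in SS (470). There the highest other splits called more genes (1631 and 1084), which points to a structure of the samples. Labels drawn at random over all 45 libraries thus seldom gave such counts. Each split shuffled all 9 labels at once, so differences among the other subtypes entered its spread and can lower its counts. The test therefore cannot say whether a single subtype differs from the rest by more than chance. For the genes that differ among the 9 subtypes it was 1 of 100 (10158, highest other 44) and for DDLPS against MLPS 1 of 56 (314, highest other 146). For TGCT against PVNS 3 of 10 splits gave as many (2, highest other 2), and the splits are too few for a share under 0.05. For MLPS against EMC 23 of 100 gave as many as the real 24, so chance is not excluded, and the highest, with 877 genes, exchanges exactly MLPS replicate 3 and EMC replicate 4, which points to a structure of the samples.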

How the results depend on the processing

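The edgeR test, the fits without the 3 libraries dominated by 1 or 2 loci, with those loci removed, and without MLPS replicate 3 and EMC replicate 4 were chosen only after the result was seen. Of 498 values of counts and list medians under an alternative, 385 stayed the same, 16 were weaker and 97 moved. A count was the same within 1.5 times and had moved otherwise. A list median was the same where its test kept its side of the threshold, and weaker where the test no longer passed. A median whose test passed in neither setting counted as the same whatever its size or sign. Of 5895 values of named genes, 5325 stayed the same, 456 were weaker, 113 stronger and 1 reversed, where a change of sign in a gene called in neither setting counts as the same. No paired analysis was possible because the labels link no sample to another. Counts below are genes called. Where a value moved or was weaker, the cause was not tested.

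With a pseudocount of 0.1 RPM the counts were 5640 for GIST WT, 134 for DDLPS, 1790 for MLPS, 50 for EMC, 259 for SS, 0 for TGCT against PVNS (limma), 125 for DDLPS against MLPS and 2 for MLPS against EMC. With 5 RPM they were 1497 for GIST WT, 959 for ESS, 1241 for MLPS, 2432 for TGCT with PVNS, 25 for TGCT against PVNS and 37 for MLPS against EMC. Without a filter they were 152 for EMC, 4 for TGCT against PVNS and 8 for MLPS against EMC, and with a filter at 5 RPM 3 for MLPS against EMC. Median-of-ratios scaling gave 148 for DDLPS, 9 for TGCT against PVNS and 5 for MLPS against EMC. Quantile normalization gave 1695 for GIST WT, 140 for DDLPS, 141 for EMC, 3067 for TGCT with PVNS, 5 for TGCT against PVNS and 6 for MLPS against EMC. Robust estimation gave 14 for MLPS against EMC. Array quality weights gave 2119 for GIST WT, 3529 for DDLPS, 670 for EMC, 2650 for EWS, 3071 for SS, 2155 for TGCT against PVNS, 1537 for DDLPS against MLPS, 289 for MLPS against EMC and 15594 genes that differ among the subtypes.

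The shared block alone, with fewer libraries, gave 696 for ESS, 278 for DDLPS, 662 for MLPS, 34 for EMC, 156 for SS, 1 for MLPS against EMC, 2107 genes that differ among its 6 subtypes and 16 of 22 libraries nearest to their own label. A low side that weighs libraries equally gave 473 for EMC. The fit of 2 groups alone gave 841 for TGCT against PVNS, 64 for DDLPS against MLPS and 0 for MLPS against EMC (limma). Without the 3 dominated libraries the counts were 1434 for GIST WT, 1360 for DDLPS, 1319 for EWS, 731 for SS, 472 for DDLPS against MLPS and 10 for MLPS against EMC. With their loci removed they were 2499 for GIST WT, 537 for DDLPS, 135 for EMC and 12 for MLPS against EMC. Without MLPS replicate 3 and EMC replicate 4 they were 869 for EMC, 4 for TGCT against PVNS, 479 for DDLPS against MLPS and 594 for MLPS against EMC. EdgeR gave 1782 for GIST WT, 3030 for ESS, 1333 for EMC, 1614 for EWS, 763 for SS, 0 for TGCT against PVNS (1817 at an unadjusted p under 0.05, and 820 in limma) and 45 for MLPS against EMC.

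Leaving out 1 library at a time, counts ranged from 2306 to 4510 for GIST WT, 158 to 669 for DDLPS, 684 to 2863 for MLPS, 19 to 782 for EMC, 506 to 756 for EWS, 199 to 364 for SS, 0 to 4 for TGCT against PVNS, 127 to 395 for DDLPS against MLPS and 0 to 231 for MLPS against EMC. The median of the neuroendocrine and neuronal genes in MLPS against EMC (-0.219, adjusted p = 0.0407) lost its call with 5 RPM added (-0.064), a filter at 5 RPM (-0.244), median-of-ratios scaling (-0.215), quantile normalization (-0.134), array weights (-0.366), the shared block (-0.219) and an estimated correlation (-0.219), and ranged from -0.438 to -0.085 with 1 library left out. The adipocyte genes in MLPS (median 2.77) lost theirs with an estimated correlation (2.772). HOXC11 in ESS turned from -1.55 to 0.146 in edgeR. Depth limits the low end: in the shallowest library 1 read is worth more than 1 RPM, so genes near the filter are read there from 0 or 1 reads.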

Other observations

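The lists of this part were picked for description after their tests were seen.

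Genes of the HOX clusters, which encode position along the body axis in development, were called in MLPS, EWS and ESS, but no test of the lists below passed with an estimated correlation. In MLPS 6 of 9 HOXA genes were higher than in the other 8 subtypes, among them HOXA5 (log2 2.49 ± 0.43) and HOXA9 (2.95 ± 0.52), with a median of 1.79 relative to all genes (adjusted p = 4.3e-05, but adjusted p = 0.15 with an estimated correlation). The shared block gave 7 of 9. In EWS 4 of 8 HOXC genes were higher, and 5 over the list alone, with a relative median of 1.52 (adjusted p = 0.00187, but adjusted p = 0.466 with an estimated correlation). HOXC11 (2.70 ± 0.67) lost its call without EWS replicate 2 (2.35) or 4 (2.49), and the shared block gave 1 gene. In ESS 4 of 6 HOXD genes were higher, HOXD9 (3.47 ± 0.57), HOXD10 (2.06 ± 0.34) and HOXD11 (2.44 ± 0.54) among them, with a relative median of 1.97 (adjusted p = 6.99e-05, but adjusted p = 0.206 with an estimated correlation). Limma called 0 of them in the shared block, where HOXD9 stood at 2.54, HOXD10 at 1.93 and HOXD11 at 0.84, and edgeR on every library called 6. In ESS 4 of 8 HOXC genes were lower, with a relative median of -0.91 (adjusted p = 0.00285, but adjusted p = 0.252 with an estimated correlation), and 7 in the shared block but 1 in edgeR. HOXC10 stood at -1.84 ± 0.37, and HOXC11 at -1.55 ± 0.41 in limma and 0.15 in edgeR.

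In TGCT with PVNS, 4 of 9 neutrophil genes were higher and 1 lower, with the same counts over the list alone (adjusted p = 3.24e-05, and adjusted p = 0.0297 with an estimated correlation). FPR1, a receptor for bacterial peptides, was higher by a log2 fold change of 4.48, CSF3R by 3.83, and S100A8 and S100A9, which form calprotectin, by 3.12 and 3.06. CEACAM8 was lower (-1.49), and the granule genes MPO (-0.04) and ELANE (0.04) were not called. FPR1, CSF3R, S100A8 and S100A9 are also expressed by monocytes.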
